A study of Mus musculus with 6 samples.

How the data were processed

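Small RNA libraries from 6 mouse samples were analysed, 3 oviducts and 3 primary tumors. Per the labels' protocols, total RNA was isolated with a miRNeasy kit and the libraries were built with an Illumina TruSeq small RNA kit. Adapters were trimmed with cutadapt, per the submitters' processing notes, which state no version. Per the file headers, the counts came from BAM files of trimmed reads. The aligner, its settings, the counting program, the microRNA reference and the genome build are not given in the sources used here. How reads that match several hairpins were assigned is likewise not given.

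The deposited values are raw whole-number counts, with no normalization, per mature microRNA name. The table held 1915 mouse names and 67 names of other species. The latter carried 10 counts in total and were left out of library sizes and tests. Of the mouse names, 919 had a count in at least 1 library. Mouse counts per library were 375614, 580390 and 297039 in the oviducts and 272167, 176615 and 154002 in the tumors. A floor of 3 counts corresponded to between 5.17 and 10.1 CPM (the count scaled by library size) in the oviducts and between 11.0 and 19.5 CPM in the tumors. Single shares carry exact Clopper-Pearson 95% intervals. These intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

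Groups were taken from the labels. The series text speaks of 5 oviducts and 4 tumors, of which 3 and 3 were analysed here. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. Each library was counted as 1 replicate because the labels give it as a separate sample. No library of a group was a repeated deposit of another, the lowest chi-square per degree of freedom between their counts being 30.7, which says nothing on whether they came from separate animals. Pearson's r of log CPM, computed across microRNAs, was at least 0.971 between oviducts, at least 0.900 between tumors and at most 0.729 between the groups.

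Single microRNAs were compared with edgeR 4.0.16 in R 4.3.3, using filterByExpr with a minimum count of 10, trimmed mean of M-values (TMM) factors and the robust quasi-likelihood test. TMM factors were 0.855, 0.946 and 0.853 in the oviducts and 0.734, 1.33 and 1.49 in the tumors. The filter left 227 microRNAs, which held at least 99.3% of the mouse counts of every library, and the common dispersion was 0.170. All tests were two-sided, and adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. CPM values are TMM-scaled and are given as mean ± SD.

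A hairpin yields a 5p and a 3p strand. For each hairpin the log2 ratio of (5p count + 0.5) to (3p count + 0.5) was computed per library. Names that differ only by a copy number were pooled. Hairpins with a mean total of at least 20 counts over the 6 libraries were tested with limma 3.58.1. This ratio needs no scaling between libraries. Where a strand had 3 or fewer counts in a group, the ratio of pooled counts is given as Fisher's exact conditional odds ratio with its 95% interval. That interval too covers counting error only and leaves out the spread between libraries. The share of 5p counts among all counts with a named arm was compared with a two-sided exact permutation test over the 10 splits of the 6 samples, whose smallest possible p is 0.1. Lists of microRNAs fixed before the data were examined were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, which applied to 13 of 22 lists. Each list's count of calls is given over all microRNAs and adjusted over the list alone.

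Named microRNAs followed a rule also fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among called microRNAs with a mean of at least 100 CPM in the higher group and no overlap between the groups. It also took up to 4 tested members of each list with the highest mean CPM, the 10 hairpins with the highest counts, and the 5 largest falls and 5 largest rises of the ratio. Other members named beside a count were chosen after their values were seen.

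Alternatives included DESeq2 1.42.0, other scalings and filters, other pseudocounts, an edgeR interaction of arm and group, other set tests, the replicate number as a block, and leaving out each library. Hairpin positions came from GENCODE M21 on GRCm38, used only for locations and names. Of the 1915 mouse names, 1847 matched an annotated hairpin gene. Matching and figures used Python 3.11.15 with matplotlib 3.10.9.

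The tests were checked on simulated counts drawn from the oviduct means, the sizes of the 6 libraries and the common dispersion of 0.170. The lower agreement between the tumors was thus left out. For single microRNAs, with 189 tested, edgeR recovered 100% of 20 set to an 8-fold change and 21.1% of 19 set to a 2-fold change. It called 0 of 150 unchanged ones. For hairpins, with 128 tested, limma recovered 48.6% of 35 set to an 8-fold ratio change and called 0 of 93 unchanged ones. The edgeR interaction recovered 31.4% of these 35. A let-7 list set to fall 4-fold gave a camera adjusted p of 1.06e-21 in a fit of 198 microRNAs, and 0 of 12 other lists were called. All microRNAs outside that list were left unchanged in this check, whereas 119 of 227 were called in the data. It therefore does not show how often camera would find such a list there.

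Several rows cannot be told apart by these counts. The rows of miR-199a-3p and miR-199b-3p were identical in every library, as were those of miR-486a-5p and miR-486b-5p, of miR-28a-5p and miR-28c, and of let-7a-1-3p and let-7c-2-3p.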

Results

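MicroRNA counts were compared between 3 oviducts and 3 primary tumors of mice. MicroRNAs are short RNAs cut from hairpin precursors, and Dicer, the enzyme that makes the last cuts, releases a 5p and a 3p strand from each hairpin. The oviducts carried a normal Dicer1 allele and the D1693N allele (Dicer1+/D1693N). The tumors carried D1693N beside a knocked-out allele (Dicer1ko/D1693N). D1693N changes the RNase IIIb domain, which cuts the 5p side of the hairpin, while the RNase IIIa domain cuts the 3p side. Dicer1 lies on chromosome 12 from 104687742 to 104751952 (GRCm38), and its messenger RNA is not measured by this assay, so the genotype was taken from the labels. Libraries held between 297039 and 580390 mouse microRNA counts in the oviducts and between 154002 and 272167 in the tumors. Tissue state and genotype changed together, and a tag in the deposited column names was shared by the 3 oviducts and differed in the 3 tumors, so these cannot be told apart.

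The first question was whether the strands of the hairpins changed in opposite directions. With TMM scaling 5p microRNAs were mostly lower and 3p microRNAs mostly higher in the tumors than in the oviducts. Of 95 tested 5p microRNAs, 46 fell, 2 rose and 47 were not called. Of 110 tested 3p microRNAs, 46 rose, 11 fell and 53 were not called. The 5p rises were those of miR-126a-5p and miR-136-5p. The 3p falls were those of miR-145a, miR-148a, miR-200c, miR-222, miR-29c, miR-328, miR-34b, miR-375, miR-615, miR-676 and miR-92b. The median log2 fold change (tumor over oviduct) was -1.04 for 5p and 0.89 for 3p microRNAs, a difference of -1.93. It was -1.95, -1.90 and -1.96 in the 3 tumors taken singly, each against the mean of the 3 oviducts. The 5p set stood lower than the other microRNAs by camera (p = 9.79e-14, adjusted p = 0.0111 with an estimated correlation), and the 3p set stood higher (p = 1.16e-07, adjusted p = 0.0111 with an estimated correlation).

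**Figure D1:**
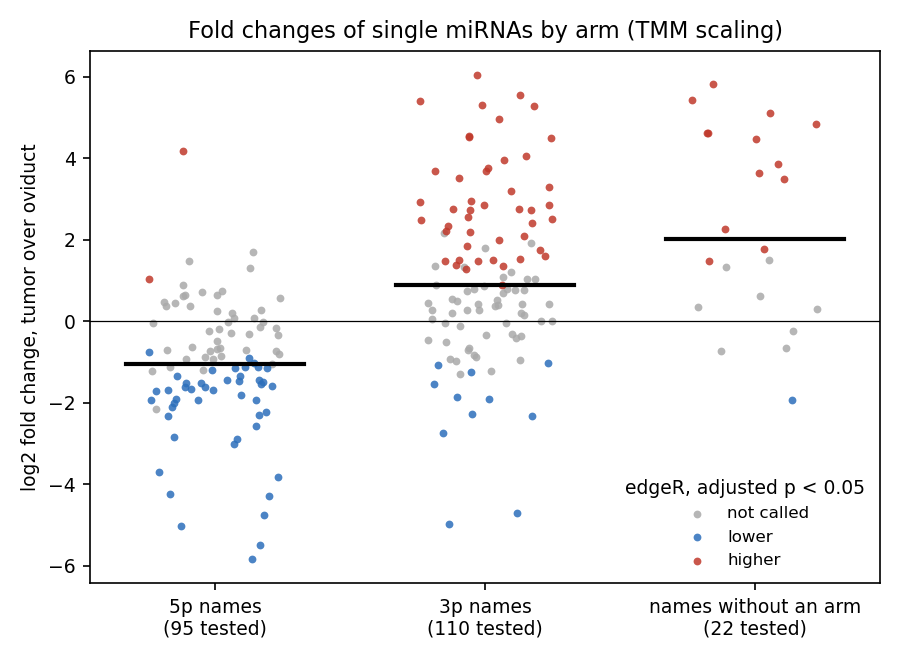
Log2 fold change (tumor over oviduct, TMM scaling) of the 227 tested microRNAs by the arm in their name, with each point a microRNA, colour marking the edgeR call and bars the medians. The medians lie at -1.04 for 95 5p names, 0.89 for 110 3p names and 2.01 for 22 names without an arm.

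In all, edgeR called 119 of 227 microRNAs, 61 higher and 58 lower in the tumors. The CPM values of the groups did not overlap for 137, where chance gives 10% for 3 against 3. The split of calls depended on the scaling. Library totals alone gave 72 higher and 26 lower, and TMM factors from 3p names alone gave 42 higher and 92 lower. The latter factors treat 3p names as unchanged on average. Values lowered and calls of rises lost with them, here and below, were therefore partly set by that choice. The median log2 fold change of all tested microRNAs was 0.20 with TMM, 0.19 with RLE factors, 0.32 with upper-quartile factors, 0.65 with library totals alone and -0.73 with TMM on 3p names. The difference between the 5p and 3p medians stayed between -1.95 and -1.91 in these scalings. The level of each arm therefore moved with the scaling, while the difference hardly did.

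Within single hairpins the 5p strand lost ground to the 3p strand. The 5p:3p ratio fell in 67 of 142 hairpins, rose in 6 and was not called in 69 (limma, adjusted p under 0.05). The median log2 change was -1.53, and 115 hairpins lay below their oviduct ratio. Of 74 hairpins with more 5p than 3p counts in the oviducts, 51 fell, and 14 of the 74 had more 3p counts in the tumors. Of 67 hairpins with more 3p counts in the oviducts, 16 fell, and 2 had more 5p counts in the tumors. The remaining hairpin, miR-677, had equal counts on its arms in the oviducts. Both strands could be tested singly for 28 fallen hairpins. In 11 of these the 5p strand fell and the 3p strand rose, in 8 only the 5p strand was called and fell, in 7 only the 3p strand was called and rose, and in 2 both fell.

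The hairpins of the miR-99 family were among the largest falls. In miR-99a (chromosome 16, 77598936 to 77599000, in an intron of Mir99ahg) the 5p strand took 93.5% ± 0.143 of the counts in the oviducts and 10.6% ± 4.64 in the tumors (SD, n = 3 each). Its pooled 5p and 3p counts went from 876 and 61 to 116 and 1095, and its log2 ratio changed by -6.95 (SE 0.59, limma adjusted p = 1.92e-05), a 124-fold fall. In miR-99b (chromosome 17, 17830188 to 17830257, in an intron of Spaca6) the 5p share went from 98.3% ± 0.356 to 35.0% ± 7.26, with a log2 change of -6.70 (SE 0.58). In miR-218, encoded in introns of Slit2 and Slit3, it went from 97.1% ± 0.843 to 17.7% ± 12.2, with a log2 change of -6.87 (SE 0.66). The miR-199a hairpins (Mir199a-1, chromosome 9, 21496495 to 21496564, and Mir199a-2, chromosome 1, 162217814 to 162217923, in an exon of Dnm3os) already had more 3p counts in the oviducts. Their 5p share went from 10.8% ± 3.46 to 0.117% ± 0.0947, with a log2 change of -7.00 (SE 0.80), which was -6.13 without tumor 1 and -7.62 without tumor 2. The 3p counts of miR-199a are identical to those of miR-199b, whose 5p counts went from 48 to 2 (odds ratio 101, exact 95% interval 26.3 to 840). In miR-196b, which overlaps an exon of Hoxa9, the 3p counts went from 1 to 35 while the 5p counts went from 858 to 136 (odds ratio 221, exact 95% interval 36.2 to 8455).

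Among the 10 hairpins with the highest counts, 5 fell and 5 were not called. The 5 falls include both miR-199a and miR-199b, whose 3p counts are the same, so they are not separate results. The 5p strand of miR-10b, encoded in an intron of Hoxd3 and Hoxd4, remained the main product, with 99.99% ± 0.00672 of the counts in the oviducts and 99.8% ± 0.181 in the tumors. Its 3p counts rose from 18 beside 188890 5p counts to 134 beside 62881, and the log2 ratio changed by -4.66 (SE 0.82, limma adjusted p = 0.000913), or -3.93 without oviduct 3 and -4.06 without tumor 3. The 3p counts of miR-26a went from 2 to 60 while its 5p counts went from 37148 to 7050 (odds ratio 159, exact 95% interval 41.9 to 1349). The 5p share of miR-181a went from 98.8% ± 0.194 to 68.7% ± 5.36, with a log2 change of -5.21 (SE 0.56). The 5 that were not called were miR-143, miR-10a, miR-27b, miR-22 and miR-148a, of which miR-148a came nearest, with a log2 change of -1.13 (SE 0.57, limma adjusted p = 0.127).

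The 6 rises rest mainly on 5p strands that were hardly counted. The 5p strand of miR-375 had 0 counts in both groups while its 3p counts went from 1696 to 36, and miR-92b had 1 and 0 5p counts while its 3p counts went from 7184 to 133. Their ratios therefore follow the pseudocount and the 3p strand. For miR-133a the 5p counts were 1 and 3, for miR-328 0 and 1, and for miR-320 0 and 12. More were counted for miR-136, 55 beside 78 3p counts in the oviducts and 570 beside 190 in the tumors, but oviduct 3 had 2 beside 10 and tumor 3 had 215 beside 7. Its log2 change of 3.02 was 1.67 without tumor 3, and its call was lost without oviduct 2, oviduct 3, tumor 2 or tumor 3. The call of miR-133a was lost with a pseudocount of 0.1, with a minimum of 5 counts and without oviduct 1, oviduct 2, tumor 2 or tumor 3, and that of miR-320 with a pseudocount of 5. An edgeR interaction of arm and group did not call miR-136 (adjusted p = 0.153). It called 2 rises, miR-320 and miR-615 (6 5p beside 146 3p counts in the oviducts, 35 beside 12 in the tumors), and 53 falls, of which 51 were also among the 67. Of the 67 falls, 8 had an arm with 3 or fewer counts over all libraries, among them miR-449a with 0 3p counts in both groups, and these too depend on the pseudocount. The other 59 had more.

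**Figure D2:**
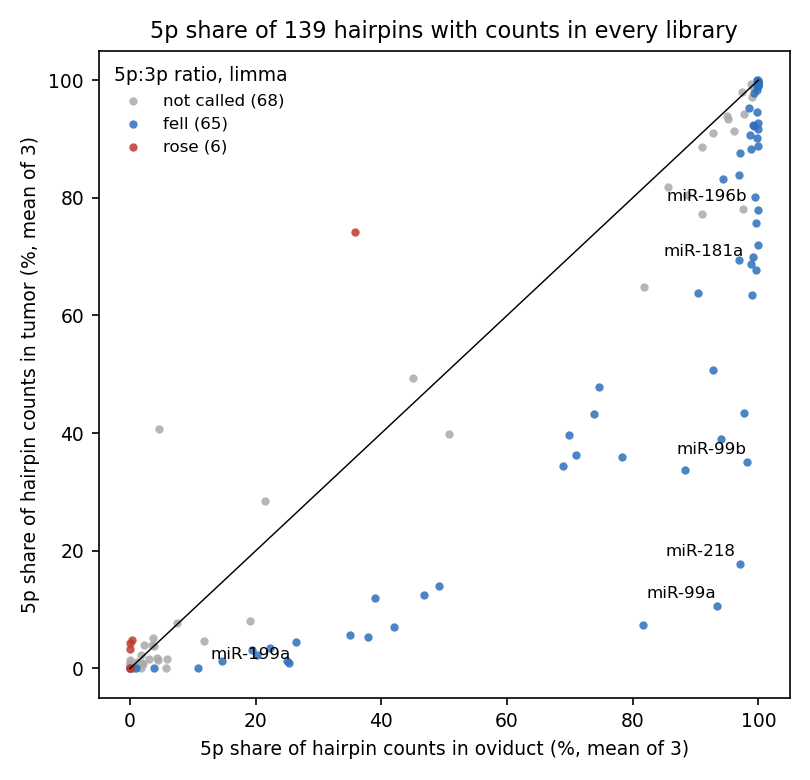
Mean 5p share of hairpin counts (percent, n = 3 per group) in the tumors against the oviducts for the 139 tested hairpins with counts in every library, coloured by the limma call, with a line of equal shares. Of the 65 fallen hairpins shown, 64 lie below the line, miR-99a at 93.5% and 10.6%, and miR-497a, with 1 and 0 3p counts, lies on the other side.

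Summed over all microRNAs, the 5p share did not separate the groups. It was 41.8% ± 1.04 in the oviducts and 38.8% ± 13.3 in the tumors (n = 3 each, two-sided exact permutation p = 1). The difference was -2.93 percentage points, and without tumor 1 it was 4.66. A single strand dominated this sum. Mouse miR-143-3p took 44.1% (95% interval 44.0 to 44.3), 45.8% (45.7 to 45.9) and 47.2% (47.1 to 47.4) of the counts in the oviducts, and 60.9% (60.7 to 61.1), 27.7% (27.5 to 27.9) and 13.9% (13.8 to 14.1) in the tumors. Without the miR-143 hairpin the 5p share was 77.5% ± 1.53 in the oviducts and 60.7% ± 3.21 in the tumors (n = 3 each, exact p = 0.1, the smallest that 3 against 3 allows). The median hairpin had a 5p share of 70.0% ± 3.68 in the oviducts and 29.7% ± 4.27 in the tumors (n = 3 each, exact p = 0.1).

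The next question was which microRNAs differed most. The largest fall was that of miR-34c-5p (chromosome 9, 51103034 to 51103110), a microRNA of multiciliated epithelial cells, from 15601 ± 3880 CPM in the oviducts to 276 ± 380 CPM in the tumors (n = 3 each). This was a 56.9-fold fall (log2 -5.83, SE 1.01, edgeR adjusted p = 0.00128), and its call was lost when no low-count filter was used (adjusted p = 0.0767). Its level was 715 CPM in tumor 1 and 47.2 and 65.9 CPM in the other tumors, and without tumor 1 the log2 change was -8.35. The neighbouring miR-34b-5p (log2 -5.01, SE 0.71) fell as well, as did miR-411-5p (log2 -5.49, SE 0.48), miR-541-5p (log2 -4.23, SE 0.72), miR-218-5p (log2 -4.29, SE 0.69), miR-199a-5p (log2 -3.83, SE 0.70) and miR-125b-5p (log2 -3.69, SE 0.41). The smooth muscle microRNA miR-145a-5p (chromosome 18, 61647825 to 61647894) fell from 2879 ± 345 to 105 ± 59.0 CPM. Falls were not limited to 5p strands, since miR-92b-3p went from 6491 ± 386 to 208 ± 104 CPM (log2 -4.97, SE 0.45) and miR-375-3p (chromosome 1, 74900658 to 74900721), a microRNA of endocrine cells, from 1495 ± 248 to 58.2 ± 64.3 CPM (log2 -4.71, SE 0.72). Without tumor 1 these log2 changes were -6.52 for miR-34b-5p, -6.09 for miR-411-5p, -5.71 for miR-92b-3p and -6.32 for miR-375-3p. Without tumor 2 that of miR-218-5p was -5.35, without tumor 3 that of miR-541-5p was -5.25, and without oviduct 3 that of miR-199a-5p was -4.44.

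The largest rises were those of 3p strands and of names without an arm. The 3p strand of miR-335 (chromosome 6, 30741299 to 30741396, in an intron of the imprinted gene Mest) rose from 17.3 ± 9.61 to 831 ± 343 CPM (n = 3 each; log2 5.54, SE 0.55, edgeR adjusted p = 3.78e-05). The 3p strands of miR-99b (38.3 ± 3.30 to 1508 ± 442 CPM, log2 5.27), miR-99a (52.7 ± 8.04 to 1678 ± 755 CPM, log2 4.97) and miR-503 (8.24 ± 10.01 to 292 ± 75.01 CPM, log2 5.31) rose too. The log2 change of miR-335-3p was 4.83 without oviduct 1 and 4.92 without tumor 1, and that of miR-503-3p lay at 4.59, 4.58 and 6.41 without oviducts 1, 2 and 3. Names without an arm took 0.852% ± 0.171 of the counts in the oviducts and 3.49% ± 0.953 in the tumors (n = 3 each, exact p = 0.1). Of 22 tested, 13 rose, 1 fell and 8 were not called. The fallen name, miR-28c, has counts identical to those of miR-28a-5p. The rises included miR-3473b (log2 5.82), miR-3473a (log2 5.43), miR-3470b (log2 5.10), miR-5100 (log2 4.85), miR-5121 (log2 4.62) and miR-6240 (log2 4.61). Without tumor 1 the values were 3.88 for miR-3470b, 3.90 for miR-5100 and 3.26 for miR-6240. Without oviducts 1, 2 and 3 that of miR-5121 was 6.20, 3.99 and 3.81, and that of miR-6240 was 6.17 without oviduct 2 and 3.79 without oviduct 3. A 20-base stretch of the hairpin was shared with at least 10 other annotated genes for 7 of the 13 risen names.

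Among microRNAs typical of cell types, falls were found in those of multiciliated cells and smooth muscle and rises in the endothelial pair. Part of these falls went with the arm. The log2 5p:3p ratio changed by -5.82 in miR-34c, -3.49 in miR-34b and -2.91 in miR-145a (limma adjusted p = 0.00103, 0.00502 and 0.0128). The falls of their 5p strands are therefore no measure of the whole hairpin. Of 6 tested members of the miR-34 and miR-449 families of multiciliated cells, 3 fell, over all microRNAs and adjusted over the list alone, and 3 were not called. These were miR-34c-5p, miR-34b-5p and miR-34b-3p, the last from 671 ± 93.3 to 231 ± 91.6 CPM (log2 -1.53, SE 0.37, edgeR adjusted p = 0.00597), whose call was lost with library totals alone (adjusted p = 0.138), while miR-34c-3p was not called (log2 -0.96, SE 0.41, adjusted p = 0.0705) but was by DESeq2, with RLE factors or TMM on 3p names, at a mean of at least 10 CPM and without tumor 1 or tumor 2. Leaving out tumor 1 gave 6 falls in this list and leaving out tumor 2 gave 5. Of 4 tested strands of the miR-143 and miR-145 hairpins of smooth muscle and fibroblasts, miR-145a-5p and miR-145a-3p (log2 -1.90, SE 0.53) fell, adjusted over the list alone as well, and the call of miR-145a-3p was lost without oviduct 2 (edgeR adjusted p = 0.0532), and its log2 change was -2.58 without oviduct 3 and -2.68 without tumor 1. The miR-143 strands were not called, with log2 values of -0.45 (SE 0.67) for miR-143-3p and -1.21 (SE 0.66) for miR-143-5p. Without tumor 1 both were called, at -2.07 and -2.56, and miR-143-5p also with TMM on 3p names. Both arms of miR-126a (chromosome 2, 26591357 to 26591429, within Egfl7), a hairpin of endothelial cells, rose, over all microRNAs and adjusted over the list alone. The 5p strand went from 7233 ± 1396 to 14835 ± 2307 CPM (log2 1.04, SE 0.28) and the 3p strand from 1172 ± 219 to 3279 ± 630 CPM (log2 1.48, SE 0.33). These calls were lost with TMM on 3p names and without oviduct 1 or oviduct 3, and that of the 5p strand also without oviduct 2 or tumor 1 and with either other low-count filter.

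Calls of epithelial and blood microRNAs depended on the setting. Of 8 tested epithelial microRNAs, miR-200c-3p (log2 -1.03, SE 0.39) and miR-141-5p (log2 -1.49, SE 0.52) fell, miR-203-3p rose (log2 1.39, SE 0.48) and 5 were not called by edgeR. Adjusted over the list alone, 0 were called. The abundant miR-141-3p (log2 -0.92, SE 0.46), miR-429-3p (log2 -0.51, SE 0.42), miR-200b-3p (log2 -0.83, SE 0.41) and miR-200a-3p (log2 -0.69, SE 0.29) missed the threshold. With no low-count filter miR-141-3p (log2 -1.20) and miR-200b-3p (log2 -1.22) were called, and at a mean of at least 10 CPM miR-200a-3p (log2 -1.01). Leaving out oviduct 3 gave a call for miR-141-3p (log2 -1.57), leaving out tumor 3 for miR-200b-3p (log2 -1.30), and leaving out tumor 1 or tumor 3 for miR-200a-3p (log2 -0.95 and -0.87). The call of miR-200c-3p was lost without oviduct 2, oviduct 3 or tumor 2, that of miR-203-3p without any oviduct or tumor 3, and that of miR-141-5p without any library but tumor 2. In this list 7 members were lower with TMM on 3p names and 0 with library totals alone. Among 7 tested leukocyte microRNAs 0 were called, adjusted over the list alone also 0, with miR-146a-5p nearest (log2 1.30, SE 0.50, edgeR adjusted p = 0.0536). It was called by DESeq2 (adjusted p = 0.0295), with RLE factors, upper-quartile factors or library totals alone, with identical rows kept once, with names without an arm left out, after thinning and without tumor 1. With library totals alone 3 leukocyte members were higher, and miR-223-3p was called without tumor 3. The values of miR-142a-5p (0.74), miR-342-3p (0.77) and miR-150-5p (0.09) turned negative with TMM on 3p names, that of miR-142a-5p also without tumor 2 (-0.94) and that of miR-150-5p also with either other low-count filter, with the replicate block and without oviduct 1, oviduct 2 or tumor 2. Of 3 red cell microRNAs only miR-451a rose (log2 1.76, SE 0.65, edgeR adjusted p = 0.0449), 0 adjusted over the list alone, and its value was 0.42 without tumor 1. Its call was lost on leaving out any library but tumor 2, with RLE factors or TMM on 3p names, at a mean of at least 10 CPM and with the replicate number as a block. The indistinguishable miR-486a-5p and miR-486b-5p had a log2 value of -0.01 (SE 0.62), whose sign varied with the scaling, and without tumor 1 it was -1.56 (adjusted p = 0.00353). The striated muscle microRNA miR-133a-3p was not called (log2 -1.23, SE 0.77), but was without tumor 1 (log2 -2.97). The neuroendocrine list had 1 tested member, miR-375-3p, which fell. The neural miR-128-3p was not called (log2 0.69, SE 0.59, or -0.15 with TMM on 3p names and 0.04 without oviduct 1), and liver miR-122 had 0 counts in both groups.

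**Figure D3:**
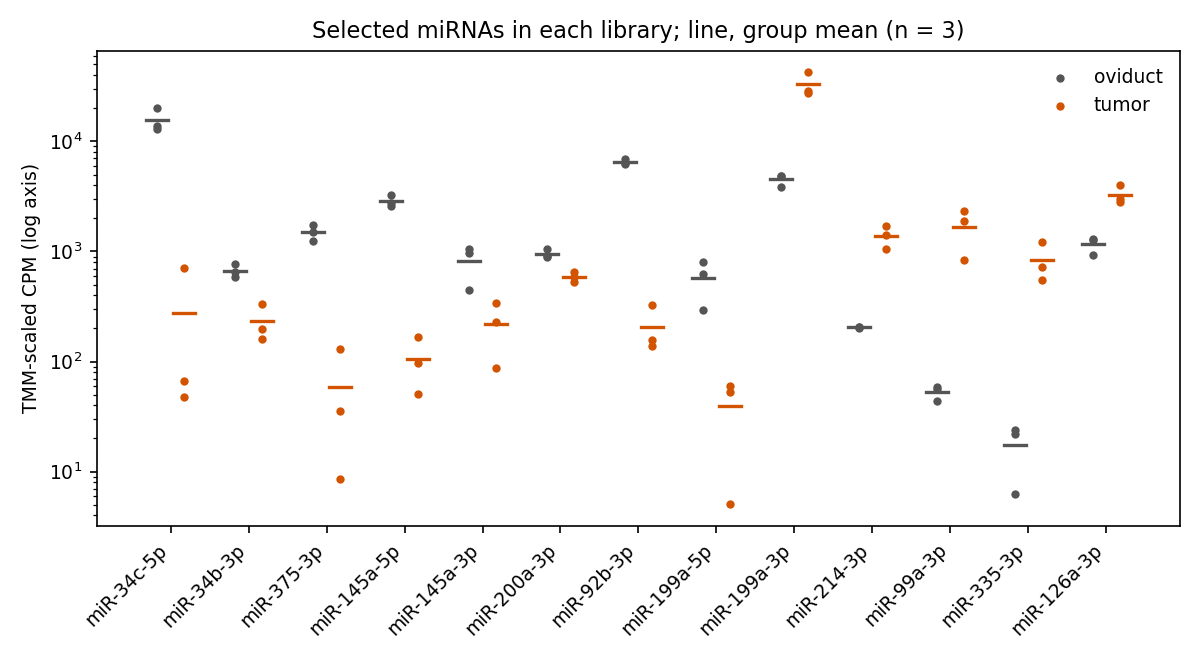
TMM-scaled CPM (log axis) of 13 selected microRNAs in each library, points for the 3 oviducts and 3 tumors and lines for group means. The means of miR-34c-5p lie at 15601 and 276 CPM and those of miR-99a-3p at 52.7 and 1678 CPM.

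The remaining lists follow families and clusters. Of 9 tested let-7 and miR-98 guide strands, associated with differentiated cells, 5 fell, 0 rose and 4 were not called, against 6 falls adjusted over the list alone. The most abundant, let-7f-5p, went from 18350.5 ± 3375 to 7176 ± 141 CPM (log2 -1.35, SE 0.27, edgeR adjusted p = 0.00204) and let-7i-5p fell less (log2 -1.02, SE 0.37), a call lost without oviduct 3 or tumor 3, with upper-quartile factors or library totals alone, with the replicate number as a block, with names without an arm left out and after thinning, while let-7c-5p (log2 -0.73, SE 0.29) and let-7a-5p (log2 -0.69, SE 0.30) missed the threshold and were called with either other low-count filter, with TMM on 3p names and without tumor 1 (log2 -1.07 and -0.99), let-7a-5p also without oviduct 1 (log2 -1.13). Of the 9, 3 fell without oviduct 3 and 7 without tumor 1. With library totals alone 0 of the 9 were called, and with TMM on 3p names 8 fell. Of 5 let-7 3p strands, 2 rose, the same number adjusted over the list alone, namely let-7a-1-3p and let-7c-2-3p, which have identical counts (log2 2.73, SE 0.47). The values of let-7b-3p (0.79, SE 0.49) and let-7d-3p (0.29, SE 0.32) were not called and were negative with TMM on 3p names, that of let-7d-3p also with either other low-count filter and without oviduct 1. In the list of miR-199, miR-214 and miR-140 strands of stroma and cartilage, 3 of 6 rose and 2 fell, the same counts adjusted over the list alone, and the split followed the arm. The shared miR-199a-3p and miR-199b-3p counts rose from 4541 ± 585 to 32951 ± 8227 CPM (log2 2.86, SE 0.30) and miR-214-3p from 204 ± 1.45 to 1384 ± 323 CPM (log2 2.76, SE 0.33). In contrast miR-199a-5p and miR-214-5p fell, the latter a call lost without any library but tumor 3, and miR-140-3p had a log2 value of -0.01 (SE 0.29) and was called at -0.88 with TMM on 3p names.

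Of 7 tested microRNAs of the Hox clusters, miR-10b-3p (log2 3.76, SE 0.75) and miR-196b-3p (1 count in the oviducts, 35 in the tumors) rose. Their list mates miR-196a-5p (log2 -3.0, SE 0.88), miR-196b-5p (log2 -1.92, SE 0.35) and miR-615-3p (log2 -2.75, SE 0.65) fell, and miR-10b-5p (log2 -0.87, SE 0.35) and miR-10a-5p (log2 0.38, SE 0.35, or -0.55 with TMM on 3p names and -0.07 without oviduct 3) were not called by edgeR. The fall of miR-10b-5p was called with no low-count filter (log2 -1.14), at a mean of at least 10 CPM (log2 -1.23), with TMM on 3p names, without oviduct 1 (log2 -1.24) and without tumor 1 (log2 -1.46). Adjusted over the list alone 2 rose and 4 fell. The call of miR-196a-5p was lost without oviduct 2 (edgeR adjusted p = 0.0664), and its log2 change was -4.64 without tumor 2. Of 10 tested microRNAs of the imprinted Dlk1-Dio3 region, 3 rose and 2 fell, against 4 and 2 adjusted over the list alone. The rises were those of miR-136-5p (44.8 ± 33.1 to 848 ± 312 CPM, log2 4.19, SE 0.64, or 3.43 without oviduct 3), miR-300-3p and miR-409-3p, and the falls those of miR-411-5p and miR-541-5p, whereas miR-127-3p (log2 1.03, SE 0.66, called at 1.43 without tumor 3 and at 1.30 with library totals alone) and miR-434-3p (log2 0.90, SE 0.80) were not called. Tumor 3 stood apart here, with 1553, 2007 and 203 counts of miR-127-3p in tumors 1, 2 and 3, 62, 62 and 3 of miR-300-3p and 64, 85 and 5 of miR-409-3p, and the CPM values of these 3 overlapped those of the oviducts. In this region 7 rose without tumor 3 and 1, miR-136-5p, without any other library, 6 rose with library totals alone, 2 with upper-quartile factors and 1 with TMM on 3p names, while 2 fell in each of these.

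In the growth-associated miR-17, miR-106a and miR-106b clusters, miR-25-3p (log2 1.74, SE 0.36) and miR-106b-3p (log2 3.21, SE 0.55) rose out of 6 tested, the same count adjusted over the list alone, and 5 of 10 rose without any 1 oviduct or tumor 1 and 4 of 7 without tumor 2. All of these were 3p strands. The log2 5p:3p ratio of miR-106b changed by -3.40 (SE 0.78, limma adjusted p = 0.00462), and miR-106b-5p was not called (log2 -0.15, SE 0.49). The rises therefore cannot be told apart from the shift between the arms. In these clusters miR-92a-3p (log2 0.20, SE 0.29) was not called by edgeR, and with TMM on 3p names its value was -0.70 (adjusted p = 0.0483), while miR-93-5p (log2 0.26, SE 0.32, or -0.63 with TMM on 3p names) was not called. The value of miR-92a-3p was also negative, from -0.12 to -0.02, with either other low-count filter and without oviduct 1, oviduct 3 or tumor 3. That of miR-93-5p was also negative with no low-count filter (-0.08) and at a mean of at least 10 CPM (-0.03). In the list of miR-210, miR-21a, miR-31 and miR-221 and miR-222, often raised in tumors, miR-21a-3p rose (log2 2.21) and miR-222-3p fell (409 ± 36.3 to 83.6 ± 25 CPM, log2 -2.28, SE 0.41), 1 each adjusted over the list alone as well, and the rise was lost without oviduct 2 or oviduct 3 and with TMM on 3p names. The 4 others were not called, among them miR-21a-5p (log2 0.64, SE 0.37), miR-221-3p (log2 0.51, SE 0.46) and miR-31-5p (log2 0.48, SE 0.35), whose values were negative with TMM on 3p names, that of miR-221-3p also without tumor 3 (-0.30). Of 3 microRNAs made outside the usual pathway, miR-451a rose, with the losses of its call given above, and miR-320-3p (log2 0.39, SE 0.32) and miR-484 (log2 0.61, SE 0.41) were not called, with 0 called adjusted over the list alone. The values of miR-320-3p and miR-484 were negative with TMM on 3p names (-0.51 and -0.30). Neither miR-182-5p (log2 0.45, SE 0.31) nor miR-183-5p (log2 0.89, SE 0.43) of their cluster was called, but miR-183-5p was with names without an arm left out and after thinning. With TMM on 3p names the values of miR-182-5p and miR-183-5p were -0.43 and -0.002. The embryonic miR-290 and miR-302 clusters (2 counts in the oviducts, 6 in the tumors), the H19 and Igf2 microRNAs (2 and 11) and the X-linked miR-506 family (5 and 8) were too sparse to test.

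By camera 0 of 13 lists passed the threshold after adjustment, and 3 had an unadjusted p under 0.05. By camera, run in limma, these were the multiciliated list with its 6 members (unadjusted p of 0.0137, adjusted p of 0.159), smooth muscle (0.0245 and 0.159) and let-7 guides (0.0440 and 0.191), all with lower members in the tumors on balance. With an estimated correlation 0 passed (adjusted p = 0.719, 0.719 and 0.855 with an estimated correlation). After each arm was centred on its median 0 of the 13 passed cameraPR and 1 had an unadjusted p under 0.05, the values for these 3 lists being 0.0721, 0.0311 and 0.788. The let-7 guides, 9 5p strands, were thus not shown to fall beyond their arm. The fry test, which asks only whether a list's members move one way, called 7, namely these 3 and let-7 3p strands, the noncanonical list, the miR-17 clusters and the stromal list. By camera, all of these 3 passed without oviduct 1 or at a mean of at least 10 CPM, and the 2 lists of multiciliated cells and smooth muscle passed without tumor 1. Median and mean differed in sign for the red cell list (-0.01 and 0.58) and the Hox list (-0.87 and 0.14), for which camera p-values were 0.967 and 0.541.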

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

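Identical rows kept once, names without an arm left out, thinning, and hairpins with an identical row left out were chosen after seeing the data. The count of called microRNAs stayed within 1.5 times 119 under each alternative, from 98 with library totals alone to 174 of 919 with no low-count filter, and lay between 105 and 142 when a library was left out. None of the 119 calls had the opposite sign in any alternative. DESeq2 called 128, of which 116 were shared. The number lower was 26 with library totals alone and 92 with TMM on 3p names, and the number higher 98 without a filter, against 58 and 61. These scalings moved the median of all fold changes from 0.20 to 0.65 and -0.73, and with no filter more names are tested. The value of miR-92a-3p turned from 0.20 to -0.70 with TMM on 3p names. The difference in the 5p share of all counts lay between -7.89 and 4.66 points when a library was left out, positive only without tumor 1, and was -26.1 without the 5 most abundant hairpins. Fallen hairpins numbered 49 to 62 when a library was left out, 49 with a pseudocount of 0.1, 74 with a pseudocount of 5, 81 with a minimum of 5 counts (189 tested), 45 with a minimum of 100 (87 tested) and 54 after thinning, of which 47 were among the 67. Risen hairpins numbered 2 by the edgeR interaction, against 6. Of the 6 only miR-320 was called there, beside miR-615, and the cause was not tested. The difference between 5p and 3p medians was -1.52 with no filter, -2.09 at a mean of at least 10 CPM, -2.0 at 100 CPM and -2.73 for hairpins with both arms tested, and lay between -2.36 and -1.76 when a library was left out. The cause was not tested. The number of lists called was 7 by fry, 3 at a mean of at least 10 CPM and between 0 and 3 when a library was left out, 3 without oviduct 1 and 2 without tumor 1. For these the cause was not tested. Replicate numbers shared between groups did not pair the samples, since same-numbered deviations correlated at -0.05, 0.09 and -0.14. With the replicate number as a block 108 microRNAs (55 higher, 53 lower) and 63 hairpins (5 higher, 58 lower) were called, the 5p share differed by -2.93 points, the medians by -1.90, and 0 lists passed. Among named results, 31 microRNA values and 11 hairpin values lost their call in an alternative, and 50 microRNA and 15 list values gained one, counted over all alternatives. Depth limits the rare strands: the floor of 3 counts lay at up to 19.5 CPM in tumor 3.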

Other observations

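The microRNAs given in this paragraph were chosen after their values were seen. Members of a cluster of neighbouring hairpins went in opposite directions in some clusters and not in others. In the cluster that holds miR-322, miR-503, miR-542 and miR-351, miR-322-3p (log2 1.84, SE 0.33), miR-503-3p (log2 5.31, SE 0.80) and miR-542-3p (log2 3.68, SE 0.56) rose in the tumors, and miR-351-5p fell (1461 ± 231 to 390.0 ± 175 CPM, log2 -1.90, SE 0.39). Its miR-322-5p had a log2 value of 0.21 (SE 0.38) and was not called by edgeR. The rises here were of 3p strands and the fall was of a 5p strand, so the split followed the arm. The log2 5p:3p ratio fell in miR-322 (-1.69), miR-503 (-3.15), miR-542 (-3.65) and miR-351 (-2.69, with 1 3p count in each group). In the cluster of miR-34b and miR-34c, by contrast, 3 of 4 tested strands fell and 0 rose, miR-34b-3p (log2 -1.53) as well as miR-34b-5p (log2 -5.01). The hairpin of miR-126a stood apart from most others, since both arms rose and its 5p share was 85.6% ± 4.4 in the oviducts and 81.8% ± 2.89 in the tumors (n = 3 each; log2 ratio change -0.44, limma adjusted p = 0.567). The miR-125b hairpin changed its main arm, from a 5p share of 81.6% ± 2.96 to 7.38% ± 3.12, and the 5p share of miR-100 went from 99.6% ± 0.202 to 75.8% ± 4.91.

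Tests of scaling for both patterns below and of the column tag, the limit to hairpins counted on both arms with its shares without single libraries, and the comparisons of names without an arm by count and with those that did not rise were chosen after the result was seen.

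The fall of 5p and rise of 3p microRNAs in the tumors was weighed against technical explanations. Scaling between libraries was argued against for the shift of 5p relative to 3p strands. The ratio within a library, which has no scaling, fell in 11.2 hairpins for each hairpin in which it rose. That ratio cannot show whether 3p microRNAs rose in themselves. With TMM on 3p names 42 microRNAs were still higher and 92 lower. That scaling treats 3p names as unchanged on average, so it cannot decide whether 3p microRNAs rose as a set. Scaling stays open for the rise of 3p microRNAs taken as a set. Thinning every library to the smallest total argued against depth, since 70.1% of the 67 fallen ratios (47) were still called, among 54 falls and 5 rises in all. Loss of oviduct cell types rich in 5p guides would lower both strands of their hairpins and leave the 5p:3p ratio as it was. The ratio fell in 67 of 142 hairpins, 59 of them with over 3 counts on each arm, and rose in 6. This argues against such a loss as the source of these falls. Loss of cell types that differ in how they use the strands of the same hairpin stays open. The bound set beforehand against the loss of cell types covered all 67 hairpins with more 3p counts in the oviducts. Of these, 64.2% lay below their oviduct ratio (exact 95% interval 51.5 to 75.5), short of that bound. Among the 45 with over 3 counts on each arm the share was 71.1% (55.7 to 83.6), above the bound. It was below the bound without oviduct 3 (64.1%, 47.2 to 78.8) and without tumor 2 (65.9%, 50.1 to 79.5). These intervals treat hairpins counted in the same libraries as independent. Of 62 hairpins with more 5p counts in the oviducts and over 3 counts on each arm, 98.4% lay below their oviduct ratio. A library batch cannot be told apart from the groups, because 0 libraries carried the column tag of the other group. The genotype, D1693N without a normal allele, stays among the open explanations and was not tested, since no tumor with a normal allele and no oviduct without it was analysed here.

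The rise of names without an arm was weighed in the same way. Scaling was argued against, since in the tumor where the gap was smallest their median log2 change still lay 0.74 above that of 3p names. Reads of repeats or other repeated transcripts may account for part of it: 53.8% of the 13 risen names (7) shared a 20-base stretch of their hairpin with at least 10 other genes, against 1.02% of 196 names with an arm (Fisher's exact p = 1.88e-08) and 12.5% of 8 names without an arm that did not rise (Fisher's exact p = 0.0850). Both tests count names as independent, which miR-3473a, miR-3473b and miR-3473f need not be. The hairpin of miR-3470b shared such a stretch with 618 other genes, those of miR-3473b and miR-3473f with 390 and that of miR-3473a with 117, while the hairpin of miR-5121 overlaps the genes Snord33 and Rpl13a. These 7 held 5.84% of the tumor counts on names without an arm, while miR-1957a (4 other genes) and miR-5099 (0) held 74.7%, so for these, for miR-6240 (3) and for miR-5100, miR-5121 and miR-451a (0) the rise stays open, and no biological explanation was tested.

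The miR-143-3p share of tumor 1, 60.9% against 27.7% and 13.9% in the other tumors, might come from normal tissue in that sample. Oviduct tissue was argued against as its source, because 34 microRNAs higher in the oviducts, chosen without tumor 1, implied a share with an upper quartile of 4.87%, while miR-143-3p would need 161%, although miR-133a-3p implied 72.9%, miR-143-5p 62.5% and miR-449a-5p 54.8%. Normal smooth muscle was argued against as the whole source, since the upper bound of the excess of miR-145a-5p, from the neighbouring hairpin, was -4.82% of the oviduct level and miR-145a-3p implied 6.81%. All these shares rest on counts scaled by totals alone, where the large miR-143-3p share of tumor 1 lowers the other microRNAs. With TMM scaling miR-145a-5p stood at 50.4, 167 and 96.7 CPM in tumors 1, 2 and 3. The values of miR-145a-3p were 342, 228 and 87.9 CPM, so its implied share depends on the scaling. A small share of oviduct cells stays open, since miR-34c-5p stood at 715 CPM in tumor 1, as do striated muscle, for which miR-133a-3p stood at 518 against 157 CPM (scaled by totals alone), and other cell types. The tumor's own expression stays open too, and no biological explanation was tested.

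Neighbouring hairpins were also tested for the hypothesis that tumor and oviduct differ in transcription of whole clusters. After each arm was centred on its median, 0 of 16 clusters passed the cameraPR threshold. The lowest unadjusted p values were 0.00963 for miR-34b and miR-34c and 0.0311 for miR-143 and miR-145a, both lower in the tumors. The bound written beforehand, that no cluster passes, was too strict: with statistics exchanged between microRNAs of the same arm (100 exchanges) and every member of a cluster then shifted, a check chosen after the result was seen, the test called 30.9% of clusters shifted 4-fold and 68.8% of those shifted 8-fold. The transcription of whole clusters therefore stays open, and without arm centring the list of the miR-143 and miR-145a strands had a camera adjusted p of 0.159 (0.719 with an estimated correlation) and passed at the preset correlation only in some alternatives, without oviduct 1, without tumor 1 and at a mean of at least 10 CPM.

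The 6 samples can be divided into groups of 3 in 10 ways, too few for a share under 0.05. For single microRNAs the real division called 119 and the highest other 0, so 1 of 10 reached the real count. For hairpins the real division called 73 and the highest other 0, again 1 of 10. For lists the real division called 0 and the highest other 5, so 10 of 10 reached the real count. Any division reaches a count of 0, so the comparison decides nothing for lists. The division with 5 lists mixed the groups and called 0 single microRNAs, a limit on the camera p-values at the preset correlation.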
